A study of Mus musculus with 8 samples.

How the data were processed

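Total RNA of sorted colonic and splenic mononuclear phagocytes was extracted with a column kit, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols, with 1 array for each of 8 groups. The deposited values were on a log2 scale, read from their range of 3.37 to 14.31. Per the submitters' processing notes, the authors used RMA, which corrects background, quantile normalizes and summarises probes into probe sets, and Partek. Versions, settings and the genome build were not given in the sources used here. Groups, tissue, condition and sex were taken from the labels, which name no replicate and do not say how many mice gave each sample.

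The table held 35399 probe sets. Of these, 21789 carried 1 gene symbol in the platform annotation, 1621 carried several, and 11989 were not listed there and stayed unnamed. Entrez identifiers of 21698 probe sets matched the RefSeq gene table, which changed 0 symbols. Genes were named only from probe sets with 1 symbol, which gave 19938 genes. Where a gene had more than 1 probe set, as 999 genes did, the one with the highest mean was used. Ly6c1 and Ly6c2 shared their probe sets and are not analysed here. Some other members of the gene lists are not reported here.

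Single arrays were compared as differences of deposited log2 values with no test. A gene entered a comparison when the brighter of both arrays was at or above that array's median over all probe sets, and a log2 difference of at least 1 counted as 2-fold. The 9 comparisons were named from the labels, and the pair of steady-state colonic CX3CR1hi arrays served as a yardstick (SD over genes 0.396, median absolute difference 0.190). There were 34 gene lists, including marker lists of other cell types and a check of the sex label, naming 539 members of which 493 were measured. Each list's median was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, and lists with fewer than 4 genes past the filter got no percentile. Lists of pancreatic acinar and islet genes were added after the values were seen. Neither islet gene exceeded 4.82 in any colonic array. For the position between monocyte and macrophage, genes were chosen on the arrays labelled female and measured on those labelled male.

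Populations were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 10673 genes at or above the array median in at least 2 arrays, with all 8 arrays in the fit, 5 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Median standard errors were 0.167, 0.167 and 0.192 for CX3CR1hi against splenic, CX3CR1int against CX3CR1hi and CX3CR1int against splenic. The number of arrays limits the precision. Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated per list. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

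Named genes were chosen by rule. Per single-array comparison these were the 6 genes with the largest positive and the 6 with the largest negative difference past the filter, up to 4 members of each list with the largest absolute difference, and a set of focus genes. Per population contrast these were the 10 highest and the 10 lowest fold changes past the threshold, with the same additions. Predicted genes and clones, olfactory and vomeronasal receptors, small RNAs, histone clusters and antigen receptor segments were left out of the largest differences. The groups, comparisons, tests, lists, naming rule and all alternatives except those said to be added were fixed before the data were examined.

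The population test was tested on simulated data with the real arrays' means and spread and 200 changed genes per contrast among 10673. For CX3CR1hi against splenic cells it recovered 66 of 100 genes changed by a log2 of 1 and 95 of 100 changed by 2, with 12 false among 173 calls. For CX3CR1int against CX3CR1hi cells it recovered 60 and 90 of 100, with 10 false among 160 calls. For CX3CR1int against splenic cells it recovered 58 and 80 of 100, with 10 false among 148 calls. The simulated noise was independent between genes and arrays, whereas the real arrays of a population differed in colitis, origin, Ly6C or sex. The real contrasts also called far more genes, 5466, 3186 and 2605 in the same order. These figures therefore do not give the recovery or false calls of the test on the real data.

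Alternatives were no brightness filter and one at the 75th percentile, the mean of a gene's probe sets, arrays centred on their medians, a repeated quantile normalization and other comparison arrays. For the population test they were sex as labelled as a block, each contrast's arrays alone, a trended and robust prior, a 2-fold minimum and leaving out each array in turn. The sex block coded the steady-state splenic array as female, although it carried Y-linked RNA as well as Xist. Added after seeing the data were counts over genes bright in both splenic arrays, counts without marker genes of other cell types, list medians and members against the other steady-state CX3CR1hi array, and the colitis splenic array as the comparison for resident macrophages.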

Results

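Gene expression was measured on Affymetrix arrays in mononuclear phagocytes, the monocytes, macrophages and related cells that engulf material and present antigen. The cells were sorted by flow cytometry from the lamina propria of the colon, the tissue under its epithelium, and from the spleen. The mice were C57BL/6 with a green fluorescent protein in place of 1 copy of Cx3cr1, the fractalkine receptor gene, so that fluorescence reported CX3CR1. Part of the mice were at steady state, and the others were at day 4 of colitis induced by dextran sodium sulphate, a compound that damages the colonic epithelium. There were 8 groups with 1 array each. At steady state these were colonic CX3CR1hi resident macrophages, colonic CX3CR1hi macrophages reconstituted from monocytes, splenic Ly6Chi monocytes and colonic CX3CR1hi F4/80hi cells. In colitis they were colonic CX3CR1hi F4/80hi, CX3CR1int Ly6Clo and CX3CR1int Ly6Chi cells and splenic Ly6Chi monocytes. The resident, reconstituted and steady-state splenic arrays were labelled female and the other 5 male. Array medians lay between 5.77 and 5.87 on the log2 scale.

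Because each group had 1 array, no difference between single arrays has a replicate check, and "higher" and "lower" describe those arrays alone. Differences are log2 values, the first-named array minus the other, and 2-fold corresponds to a difference of 1. The percentile beside a gene list is that of its median among 10000 random lists of genes of similar brightness on the same pair of arrays. By the labels, the steady-state colonic CX3CR1hi arrays F4/80hi and resident came nearest to a repeat, although the label for sex differed. Of 10384 genes, 29 were at least 2-fold higher and 349 lower in the F4/80hi array, 378 in all. This was more than for reconstituted against resident macrophages (183) or for colitis against steady state in F4/80hi cells (151). The SD of the differences over genes was 0.396 against 0.361 and 0.316, so neither of those comparisons exceeded the distance within this pair. Against the reconstituted array, the steady-state F4/80hi array had 57 genes higher and 159 lower. The F4/80hi and resident pair was thus a wide yardstick. Its correlation (0.975) was the lowest among the steady-state CX3CR1hi pairs, the others standing at 0.9765 and 0.979. Over genes bright in both splenic arrays, a choice made after the values were seen, the pair had 23 higher and 47 lower, against 34 and 18 for the first and 39 and 13 for the second comparison. The highest were the Y-linked genes Eif2s3y (5.42), Uty (4.69) and Kdm5d (3.51), followed by Retnla (2.00), which encodes a secreted resistin-like protein, and Snhg17 (1.96) and DQ267102 (1.87). The lowest were Xist (-7.54), the RNA that silences an X chromosome in females, and the pancreatic enzyme genes Cpa1 (-4.34), Ctrb1 (-4.29), Cpb1 (-3.76), Ctrl (-3.55) and Rnase1 (-3.48). No member of the macrophage identity, chemokine, interferon response or MHC class II lists was 2-fold apart. Among 16 hypoxia and glycolysis genes 1 was lower, Ndrg1 (-1.01), and Vegfa, a vascular growth factor, differed by -0.92. Inflammatory mediators (median -0.37, percentile 0.37) and cell cycle genes (-0.39, percentile 0.06) were within 2-fold but low among random lists. Epithelial marker genes had a median difference of -0.76, with 4 of 16 lower, among them Slc26a3 (-1.69).

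**Figure D1:**
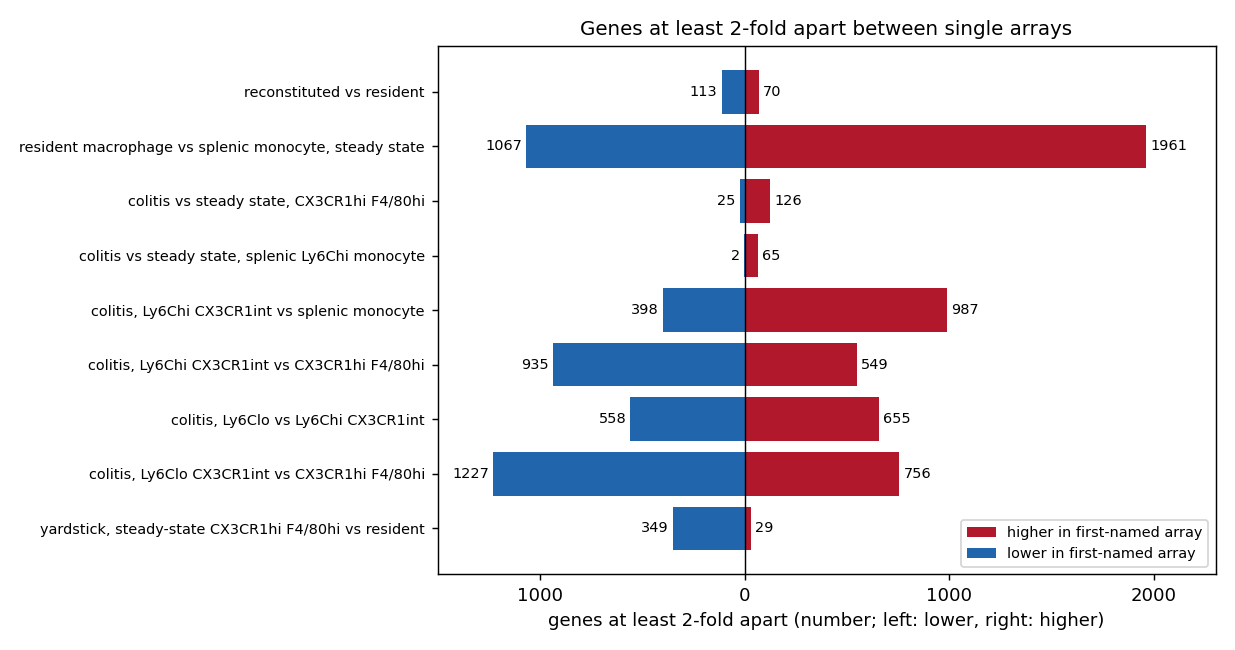
Number of genes at least 2-fold apart in each pair of single arrays, on a linear axis, with genes higher in the first-named array to the right (red) and lower to the left (blue). The counts run from 65 higher and 2 lower for colitis against steady-state splenic monocytes to 1961 higher and 1067 lower for resident macrophages against splenic monocytes.

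The comparison of reconstituted with resident macrophages asked how closely macrophages that monocytes had given rise to resembled those already in the colon. Macrophage identity genes were alike in both arrays: of 16, 15 lay within 2-fold, the median difference was -0.01 (percentile 61.3), and Cx3cr1 (10.88 against 11.21), Adgre1, which encodes F4/80 (12.05 against 12.33), and the MHC class II gene H2-Ab1 (a difference of 0.01) stood at similar levels. The exception in the list was Cd163, a scavenger receptor for haemoglobin complexes, at 5.99 against 8.22. The largest differences in favour of the reconstituted cells were Kcnma1, a calcium-activated potassium channel (12.13 against 4.19, a difference of 7.94), Mmp9, a gelatin-degrading protease (11.88 against 6.88), and Il22ra2, the soluble decoy receptor for interleukin 22 (3.84). Defa24 (2.57), an antimicrobial defensin of Paneth cells, Clec1b (2.39) and Adgrl3 (2.27) followed. In all, 70 genes were at least 2-fold higher and 113 lower among 10374.

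Of 18 anti-inflammatory and scavenger genes 3 were lower in the reconstituted array and none higher (median -0.19, percentile 0.87). Those 3 were Cd163, the hyaluronan receptor gene Lyve1 (-1.25) and Il10, the cytokine that restrains macrophage activation (9.92 against 11.01). Against the steady-state F4/80hi array Cd163 was still lower (-1.62), Lyve1 (-0.72) and Il10 (-0.64) were within 2-fold, and the list's median was -0.02, a setting added for lists after the values were seen. The C-type lectin genes Cd209f (-3.56) and Cd209a (-2.40) were also lower. Chemokine genes went both ways, with Ccl17 (1.49) and Ppbp (1.25) higher and Ccl5 (-1.48) and Ccl8 (-1.28) lower. S100a4 (1.60), Treml4 (1.66), Nr1h3 (1.12), a sterol-sensing nuclear receptor, and the macrophage elastase gene Mmp12 (1.03) were higher, and Iigp1, an interferon-induced GTPase, was lower (-1.51). Tnf (-0.77) and Il1b (-0.10) were within 2-fold, as were all 23 lysosomal genes and all 23 pattern recognition receptors. Small shifts placed the matrix remodelling (median 0.17, percentile 99.8), lipid handling (0.19, percentile 99.8), dendritic cell (0.19, percentile 99.9), immediate early (0.14, percentile 99.9), cell cycle (0.11, percentile 99.6) and ribosomal protein lists (0.11, percentile 99.4) high among random lists, although at most 2 genes in any of them were 2-fold higher. Such ranks treat the genes of a list as independent and do not show that the lists differ. Markers of other cells went both ways. Medians were -0.44 for epithelium, -0.72 for stroma and -0.42 for plasma cells (Igha -1.31), but 0.50 for neutrophils (2 of 4 higher, Mmp9 and Retnlg; percentile 100), 0.28 for endothelium (percentile 98.6), 0.36 for red pulp macrophages (percentile 99.7) and 0.16 for patrolling monocytes (percentile 97.8). Against the F4/80hi array the medians changed sign for epithelium (0.33), plasma cells (0.012) and patrolling monocytes (-0.0013). Pancreatic enzyme genes led the lower end, with Cpb1 (-3.73), Cpa1 (-3.64), Ctrb1 (-3.59), Rnase1 (-3.16) and Ctrl (-2.69), and 13 of 14 acinar genes, a list added after the values were seen, were lower. Against the steady-state F4/80hi array these 5 genes had the opposite sign, between 0.04 for Cpb1 and 0.86 for Ctrl, and the counts became 159 higher and 57 lower.

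Resident macrophages were set against splenic Ly6Chi monocytes, both at steady state, to describe how the tissue cells differed from monocytes. Complement genes were higher in the macrophages in 8 of 10: C1qa, a subunit of the complement initiator C1q, stood at 11.93 against 5.78. Mertk, a receptor for dying cells, was 4.75 higher and its ligand Gas6 5.65 higher. Il10 stood at 11.01 against 4.87. Monocyte genes were lower, among them Chil3, a chitinase-like protein (4.22 against 11.61), S100a4 (-5.92), Vcan, a matrix proteoglycan (-4.82), Fn1 (-4.19) and the monocyte homing receptor gene Ccr2 (-2.53). Serpinb10 (-8.30), Ly6a2 (-8.00), Ifitm6 (-7.28), Hp, which encodes haptoglobin (-6.81), and the neutrophil collagenase gene Mmp8 (-6.39) completed the lower end. Among 10652 genes 1961 were at least 2-fold higher and 1067 lower, but over the 9097 genes bright in both splenic arrays, chosen after the values were seen, 811 were higher and 1057 lower. That choice removes, by construction, genes dim in the spleen and higher in the colon, so the changed balance supports no conclusion.

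By list, 10 of 16 macrophage identity genes were higher and none lower (median 2.46, percentile 100), including Hpgds, a prostaglandin D synthase (6.15), and C1qc (5.89). Of 13 monocyte identity genes 11 were lower and none higher (median -2.19). Anti-inflammatory and scavenger genes were mostly higher, 11 of 18, with Stab1 (6.72), a clearance receptor, and Folr2 (4.89) as examples. Chemokine genes stood out, 14 of 16 higher with a median of 3.93, led by Ccl8 (7.23), Cxcl2 (6.78), Pf4 (6.46) and Ccl7 (5.63). Inflammatory mediators were higher as well in 7 of 13, with Ptgs2, the inducible cyclooxygenase (7.22), Il1a (6.01), Osm (4.49), Il1b (2.94) and Tnf (2.45). Interferon response genes were lower in 14 of 20 (median -1.39), among them Oas3 (-4.03) and Mx1 (-2.83), while Iigp1 was higher (2.54). MHC class II genes were higher in 6 of 11 (H2-Eb1 2.27, H2-Ab1 1.33), and the dendritic cell integrin gene Itgax was 3.35 higher, whereas Flt3, a growth factor receptor of dendritic cell precursors, was lower (-3.98). Cell cycle genes were higher in 15 of 26 (median 1.26) and the complement list had a median of 3.36. Immediate early genes, which respond within minutes to stimulation or handling, were higher in 15 of 20, among them Fosb (5.63) and Egr1 (5.01). Costimulation genes were higher in 5 of 9 (median 1.58) and matrix genes in 11 of 18, with 3 lower (median 1.65). Pattern recognition receptors were lower in 7 of 23 and higher in 4 (median -0.53), with Clec4e at -3.11. Markers of patrolling monocytes were lower in 6 of 10, including Ace (-4.87) and Spn (-3.89). Among markers of other cells all 16 epithelial markers were higher (median 5.99), as were 5 of 6 plasma cell markers (Jchain 5.37, Igha 4.49), 4 of 9 stromal markers (Dcn 5.36) and 13 of 14 acinar genes, whereas neutrophil markers were lower in 3 of 6 and higher in 2 (median -1.33, percentile 0.09). Epithelial genes supplied most of the largest differences, with Muc3 (8.40), Car1 (8.18), Lypd8 (8.17), Zg16 (8.07) and Clca1 (8.00) above Dab2, an endocytic adaptor (7.83).

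Whether CX3CR1hi macrophages differed in colitis was read from the F4/80hi arrays of male mice, colitis against steady state. Interferon response genes were higher in colitis, 5 of 20 at least 2-fold and none lower, with a median of 0.69 (percentile 100) against a median of 0.10 over all 10269 genes. They included Iigp1 (9.60 against 7.89), Ifit2 (1.27), Mx2 (1.12) and Rsad2, an antiviral radical enzyme (1.11). Some scavenger and complement genes, 3 of 19 and 3 of 12, were higher too: Cd163 stood at 9.14 against 7.60, Vsig4, a complement receptor of tissue macrophages, at 6.69 against 4.90, C4b at 8.82 against 6.78, and Serping1, the C1 inhibitor, was 1.21 higher. Inflammatory cytokine genes did not separate the arrays. None of 12 inflammatory mediators was 2-fold apart, with Tnf at 0.07, Il1b at -0.13 and Ptgs2 at -0.36, and Il6, below the brightness filter, stood at 5.57 against 5.06.

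The macrophage identity list had a median difference of 0.04, with 15 of 16 within 2-fold, and Il10 (0.07), Cx3cr1 (-0.05) and H2-Ab1 (-0.07) were at the same level. Of 19 anti-inflammatory and scavenger genes 3 were higher (median 0.32, percentile 100), Cd163, Vsig4 and Lyve1 (1.08), and Timd4, a phosphatidylserine receptor, was just under 2-fold (0.97). Complement genes were higher in 3 of 12 (median 0.26, percentile 99.2). Of 5 red pulp macrophage markers 2 were higher (median 0.95), Slc40a1, the iron exporter (1.46), and the transcription factor gene Spic (1.03), and Hmox1, which degrades haem, stood at 0.95. Fabp5 (1.31), Fn1 (1.08), Vcan (1.08), Ccl5 (1.07), the heat shock gene Dnajb1 (1.08), Clec9a (1.19) and Fscn1 (1.06) were higher, and Vegfa (-0.61) and Cxcl1 (-0.85) were within 2-fold. Chemokine genes had a median of 0.37 (percentile 100) with 1 of 17 at least 2-fold higher, and chemokine receptors of -0.14 (percentile 0.04) with none of 17 apart; against the resident array these medians were 0.19 and 0.03. Smaller shifts outside the central 95% of random lists were upward for pattern recognition receptors (0.19), lipid (0.23), lysosomal (0.13) and immediate early genes (0.17) and downward for MHC class II (-0.07), matrix (-0.02) and ribosomal protein genes (-0.07). At the extremes stood Reg3b (11.39 against 6.93) and Reg3g (10.83 against 7.41), antimicrobial lectins of injured epithelium, and the pancreatic enzyme genes Cpa1 (3.98), Ctrb1 (3.60), Rnase1 (3.07) and Cpb1 (3.06). The lowest were Pla2g4c, a phospholipase (6.14 against 9.44), Snhg17 (-1.48), DQ267102 (-1.45), the sodium exchanger gene Slc9a3 (-1.37), Cd209e (-1.28) and Apol7c (-1.26). Epithelial markers were all within 2-fold, with a median of -0.03 that was low among random lists (percentile 1.85) and -0.13 relative to all genes. Stromal markers were higher in 4 of 10 (median 0.86; Lum 1.51, Dcn 1.44, Pdgfra 1.32, Col1a2 1.06), acinar genes in 10 of 14 (median 1.34), and among neutrophil markers Retnlg was 1.39 higher. In total 126 genes were higher and 25 lower. Quantile normalization moved the median over all genes by -0.10 and gave 100 higher and 34 lower, and relative to that median the interferon list stood at 0.59 and the macrophage identity list at -0.06. Still 2-fold higher relative to it were 4 of 20 interferon, 3 of 10 stromal, 2 of 19 scavenger, 1 of 16 dendritic cell and 1 of 5 red pulp macrophage genes. No monocyte identity, chemokine, immediate early or matrix gene was. With the resident array as the steady-state array the counts were 67 and 401, and Cpa1 (-0.36), Ctrb1 (-0.69), Rnase1 (-0.40), Cpb1 (-0.71), Snhg17 (0.48) and DQ267102 (0.42) had the opposite sign. Against that array Vsig4 (1.03), C4b (1.67), Iigp1 (1.39), Ifit2 (1.29), Fabp5 (1.06), Fn1 (1.14), Dnajb1 (1.30), Clec9a (1.19), Retnlg (1.26) and Lum (1.06) were still at least 2-fold higher, whereas Cd163 (0.92), Lyve1 (0.55), Serping1 (0.85), Mx2 (0.99), Rsad2 (0.62), Vcan (0.66), Ccl5 (0.97), Fscn1 (0.59), Spic (0.89), Slc40a1 (0.07), Dcn (0.88), Pdgfra (0.94) and Col1a2 (0.76) were not. The interferon list had a median of 0.55 and the scavenger list of 0.24, and epithelial markers of -0.77.

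Colitis was compared with steady state in splenic Ly6Chi monocytes as well, to see whether monocytes outside the colon differed. Most genes were alike, and the correlation across 11106 genes was 0.992, the highest of the 28 pairs of arrays. Among the genes furthest apart, higher in the colitis array, were Rgs1, a regulator of G protein signalling (9.73 against 5.78), Ptgs2 (8.78 against 5.03) and the chemokine genes Ccl3 (11.51 against 8.12), Cxcl2 (2.96) and Ccl2 (2.73). Chil1, a chitinase-like glycoprotein, stood at 11.57 against 8.05. Immediate early genes were higher in 10 of 19 (median 1.01, percentile 100), including Fosb (3.16), Jun (2.12), Egr1 (2.00) and Fos (1.78). Only 65 genes were at least 2-fold higher and 2 lower among 9469.

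Monocyte genes were alike in both arrays. All 13 monocyte identity genes were within 2-fold (median 0.04), as were all 23 pattern recognition receptors, 23 lysosomal and 24 cell cycle genes, and Ccr2 differed by 0.04. Chemokine genes were higher in 5 of 13 (median 0.73; Ccl8 1.59) and inflammatory mediators in 2 of 11 (median 0.50; Osm 1.75), while Il1b (0.67) and Tnf (0.14) were within 2-fold. Interferon response genes had a median of -0.13 (percentile 0.13), with none of 19 apart. The complement genes C1qa (1.38) and C1qc (1.35), the chemerin-binding receptor gene Ccrl2 (1.79), the cytokine signalling inhibitor gene Socs3 (1.20) and Stab1 (1.03) were higher. Of the 6 epithelial markers past the brightness filter 4 were higher (median 1.67), Car1 (2.61), Muc2 (2.39), Lgals4 (1.77) and Krt8 (1.56), while over all 16 the array medians were 5.54 and 5.04. Higher too were the B cell genes Cd79a (1.37) and Ms4a1 (1.17) and the plasma cell gene Jchain (1.01). The 2 lower genes were Xist (4.58 against 10.04) and Mir15a (-1.07), the latter outside the rule for named genes and chosen after its value was seen. Phtf1os (-0.93), Hsph1 (-0.86), Cx3cr1 (-0.81), Cdx2 (-0.81) and Kcnrg (-0.77) came next. The labels for sex differed between these arrays, and the array labelled female also carried Y-linked RNA (Eif2s3y 10.28, Uty 8.46).

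In the inflamed colon, the CX3CR1int Ly6Chi cells were compared with splenic Ly6Chi monocytes to describe how these colonic cells differed from monocytes of the spleen. Inflammatory cytokine genes were higher in the colonic cells: Il6 stood at 8.78 against 4.80, Il23a, a subunit of interleukin 23, at 7.74 against 4.94, Il1a at 10.54 against 4.93 and Il1b at 12.95 against 10.46. Vegfa stood at 10.93 against 5.72, and Ptgs2 was 3.91 higher. Genes of migration and costimulation followed, with Ccr7, the receptor that guides cells to lymph nodes (9.21 against 6.69), Cd83 (3.66), Cd274, which encodes PD-L1 (2.56), Cd86 (2.04) and Cd80 (1.90). Ccr2 was nearly equal (12.32 against 12.68), whereas Cx3cr1 was lower (7.95 against 9.95). Of 10083 genes 987 were at least 2-fold higher and 398 lower, and over genes bright in both splenic arrays, a choice that removes genes dim in the spleen by construction, 387 were higher and 393 lower.

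Inflammatory mediators were higher in 10 of 14 (median 2.41, percentile 100), Tnfsf9 (3.94) and Tnf (1.02) among them, and Il10 was higher as well (2.33). Chemokine genes were higher in 13 of 18 (Cxcl2 2.86, percentile 100), costimulation genes in 5 of 9 (median 1.90), dendritic cell genes in 11 of 19 (median 1.06; Socs2 3.76) and NF-kB feedback genes in 5 of 14 (median 0.85). Hypoxia and glycolysis genes were higher in 10 of 17 (median 1.16), with Arg1, which degrades arginine (3.20), the oxygen-sensing hydroxylase gene Egln3 (2.72) and the glucose transporter gene Slc2a1 (2.33). Matrix remodelling genes were higher in 8 of 19 (median 0.83), including the transglutaminase gene Tgm2 (3.99), Timp1 (3.76) and Adam8 (3.76), and pattern recognition receptors in 6 of 23, including Cd14 (2.37), Clec4d (2.01), Nod2 (1.68) and Tlr2 (1.06). Monocyte identity genes were lower in 3 of 13 (median -0.56; Chil3 -2.07), and macrophage identity genes were higher in 4 of 15 (median 0.26; Mrc1 2.39). Serping1 (4.50), Cd63 (3.36), Iigp1 (2.72) and the cholesterol exporter gene Abca1 (2.68) were higher, and S1pr5 (-3.37), Bmx (-3.01), Abca6 (-2.79), Spn (-2.69), Ace (-2.63) and Galnt9 (-2.60) were lowest. Immediate early genes were higher in 10 of 20 (median 0.84) and complement genes in 5 of 10 (median 1.00). Adck1 led the difference (11.88 against 5.53), followed by Reg3b (6.00), Dcn (5.82), Reg3g (5.78) and Igfbp7 (5.49). Beside these groups, markers were higher for epithelium (15 of 16, median 3.52; Krt19 5.20), plasma cells (7 of 8, median 2.48; Igha 5.72, Jchain 5.43), stroma (7 of 10, median 1.34), endothelium (4 of 6, median 1.48), cytotoxic cells (3 of 4, median 1.82; Klrd1 1.88) and pancreatic acini (14 of 14, median 2.49). They were lower for patrolling monocytes (6 of 10, median -1.26) and red pulp macrophages (3 of 5, median -1.18), and neutrophil markers were lower in 3 of 6 and higher in 2 (median -0.78).

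**Figure D2:**
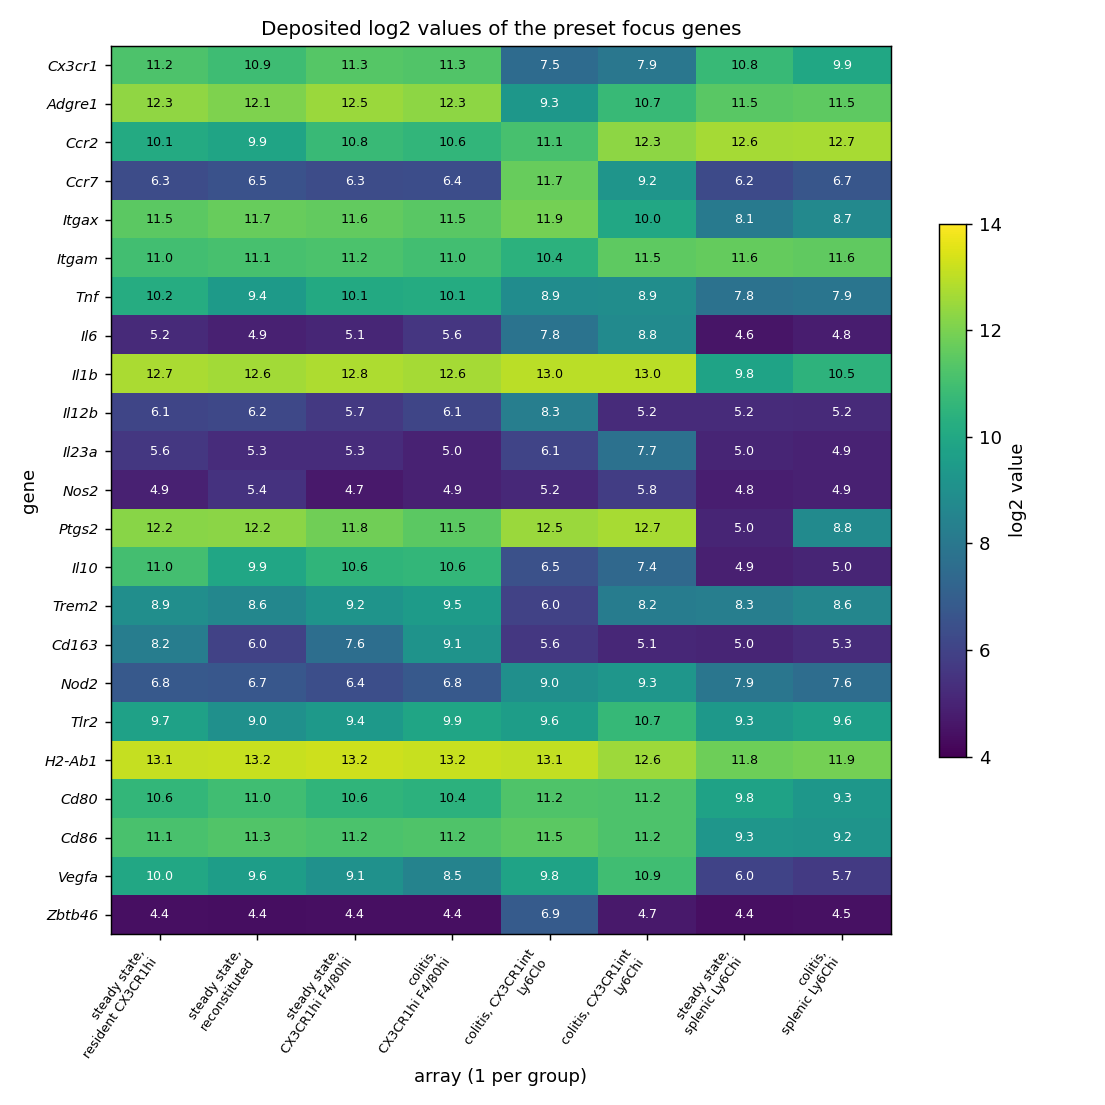
Deposited log2 values (colour and printed number) of the measured focus genes in each of the 8 arrays, 1 array per column. Il6 stands at 8.78 in colitis CX3CR1int Ly6Chi and 7.80 in Ly6Clo cells against at most 5.57 elsewhere, and Zbtb46 at 6.86 in Ly6Clo cells against at most 4.67 in the other arrays.

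The same Ly6Chi cells were next set against the CX3CR1hi F4/80hi macrophages of the colitis colon, to contrast the CX3CR1int Ly6Chi with the CX3CR1hi gate. Monocyte genes were higher in the Ly6Chi cells, among them Hp (6.18), Chil3 (4.99), Vcan (4.98), S100a4 (4.79) and Ccr2 (1.74). Macrophage genes were lower, with Cx3cr1 at 7.95 against 11.29, C1qa at -4.22, Cd163 at -4.02 and Adgre1 at -1.57. Il10 stood at 7.37 against 10.63. Il6 (3.22), Saa3 (3.08), Il23a (2.77) and the bacterial sensor genes Clec4e (4.76) and Nod2 (2.49) were higher, while Tnf was lower (-1.23) and Il1b alike (0.32).

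Of 10308 genes 549 were at least 2-fold higher and 935 lower, and over genes bright in both splenic arrays 472 were higher and 452 lower. Macrophage identity genes were lower in 13 of 16 (median -2.30), complement genes in 8 of 12 (median -1.55; C1qc -3.49), and anti-inflammatory and scavenger genes in 13 of 19 (median -1.81), including Folr2 (-4.97), Stab1 (-3.75) and Trem2 (-1.29). Monocyte identity genes were higher in 8 of 13 (median 1.74), interferon response genes in 9 of 20 (median 0.93; Oas3 3.23, Irf7 1.82) and hypoxia and glycolysis genes in 11 of 17 (median 1.14; Arg1 3.33, Vegfa 2.47). Inflammatory mediators were higher in 7 of 15 and lower in 1 (median 0.98; Ptgs2 1.21), whereas chemokine genes were mostly lower, 9 of 19 against 3 higher (median -0.85), with Ccl8 (-5.26), Ccl12 (-4.67) and Pf4 (-4.56). Dendritic cell genes were higher in 6 of 19 (median 0.43), including Flt3 (3.89), Cd209a (3.51) and Ccr7 (2.85). None of 12 MHC class II genes was 2-fold apart (median -0.32; H2-Ab1 -0.61). NF-kB feedback genes were higher in 4 of 14 (median 0.55). Chemokine receptors were higher in 5 of 19 and lower in 4 (median 0.48), and lipid genes were lower in 5 of 15 and higher in 1 (median -0.63). Lysosomal genes were lower in 4 of 23 (median -0.52; Cd63 -2.35), as was the lipid scavenger gene Cd36 (-3.65). Matrix genes split into 10 higher, including Mmp8 (4.94), and 7 lower, including Mmp13 (-5.04), of 20. Further extremes were Ly6a2 (11.51 against 4.92), Ifitm6 (6.09), Chil1 (6.05), Serpinb10 (5.91) and F10, coagulation factor X (5.34), and at the lower end Fcrls (4.06 against 10.57), H2-M2 (-6.22), Hpgds (-5.26), Cd4 (-5.12), Tanc2 (-5.10) and Vcam1 (-4.90). Epithelial markers were lower in 8 of 16 (median -1.02; Muc2 -1.15), plasma cell markers higher in 2 of 8 (median 0.70), acinar genes higher in 3 of 14 (median 0.37), and all 4 cytotoxic cell markers higher (median 1.82). Neutrophil markers were higher in 2 of 5 and lower in 1 (median 0.75), patrolling monocyte markers higher in 3 of 10 and lower in 1 (median 0.46), and endothelial markers higher in 2 of 6 (median 0.47).

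Ly6Clo cells of the CX3CR1int gate were compared with their Ly6Chi counterparts to describe the difference within the colitis CX3CR1int population. Dendritic cell and migration genes were higher in the Ly6Clo cells, with Ccr7 at 11.66 against 9.21, the chemokine genes Ccl22 at 10.69 against 5.68 and Ccl17 at 10.88 against 6.69, the actin-bundling gene Fscn1 at 4.06 higher, and Zbtb46, a transcription factor of conventional dendritic cells, at 6.86 against 4.67. Il12b, the shared subunit of interleukins 12 and 23, stood at 8.28 against 5.23. Monocyte genes were lower, among them Hp (-5.85), Vcan (-5.64), Chil3 (-4.68) and F13a1 (-3.73). Cell cycle genes were higher in 23 of 26 (median 1.90, percentile 100), including the mitotic checkpoint gene Bub1 (3.08), Top2a (2.89), Mcm6 (2.67) and Rrm2 (2.59). Tnf (-0.05) and Il1b (0.01) were equal, Il6 was just within 2-fold (-0.98), and Il23a (-1.67), Il1a (-2.30) and Saa3 (-3.80) were lower.

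Counts over 10132 genes were 655 higher and 558 lower, and over genes bright in both splenic arrays 362 and 407. The dendritic cell list was higher in 17 of 23 (median 1.95), Itgae (3.83) and Itgax (1.89) included, and the monocyte identity list lower in 10 of 13 (median -2.53; Ccr2 -1.22). MHC class II genes were higher in 4 of 12 (median 0.50), H2-Eb2 (3.70), H2-Oa (3.39) and H2-Ob (2.67) the most and H2-Ab1 little (0.54). Costimulation genes were higher in 2 of 10, Pdcd1lg2, which encodes PD-L2 (2.59), and Icosl (1.14). Pattern recognition receptors were lower in 8 of 23 (median -0.67), with Clec4d (-3.76), Tlr7 (-3.24), Clec4e (-3.08) and Tlr8 (-2.97). Lower too were inflammatory mediators in 5 of 15 (median -0.98), hypoxia and glycolysis genes in 5 of 17 (median -0.75; Arg1 -3.22, Vegfa -1.13) and matrix genes in 9 of 19 with 3 higher (median -0.89; Mmp19 -3.35). Lipid genes were lower in 4 of 15 and higher in 1 (median -0.62), and interferon response genes lower in 1 of 20 (median -0.50, percentile 0.01). Macrophage identity genes were lower in 6 of 15 (median -0.71; Adgre1 -1.44), with Hpgds higher (1.82) and Cx3cr1 close (-0.44). Msr1 (-2.98), Abca1 (-2.50) and Trem2 (-2.25) were lower and Timd4 higher (2.28). The remaining extremes were Apol7c (4.78), Mreg (4.50) and Serpinb6b (4.04) at the upper end and Ly6a2 (-6.78), Chil1 (-6.03), Ctrb1 (-5.11) and Mmp8 (-4.87) at the lower end. Marker genes were lower for plasma cells (7 of 8, median -1.71; Mzb1 -2.72, Igha -2.70, Jchain -1.75), neutrophils (3 of 4, median -2.56, with 1 higher), endothelium (3 of 6, median -1.05, with 1 higher), stroma (4 of 10, median -0.80), B cells (2 of 5, median -0.84) and acini (13 of 14, median -2.85). Epithelial markers were near level (2 of 16 lower, median -0.32), and the natural killer receptor gene Klrd1 was higher (2.44). Patrolling monocyte markers were lower in 4 of 10 and higher in 2 (median -0.50), and red pulp macrophage markers lower in 2 of 5 (median -0.90).

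Against the colitis CX3CR1hi F4/80hi macrophages, the Ly6Clo cells stood far lower in macrophage genes and higher in dendritic cell genes. Every one of 16 macrophage identity genes was at least 2-fold lower (median -3.13), with Cx3cr1 at 7.51 against 11.29, Mertk (-3.56), Cd163 (-3.54), C1qc (-3.50) and Adgre1 (-3.01). Dendritic cell genes were higher in 18 of 23 (median 2.47), led by Flt3 (11.16 against 5.14), Ccl22 (5.73), Ccl17 (5.30) and Ccr7 (11.66 against 6.36). Il10 stood at 6.46 against 10.63. Il6 (2.24), Il12b (2.19) and Nod2 (2.22) were higher and Tnf lower (-1.27).

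The counts were 756 higher and 1227 lower of 10396 genes, and over genes bright in both splenic arrays 525 and 627. Cell cycle genes were higher in 19 of 26 (median 1.40) and costimulation genes in 3 of 10 (median 0.82; Pdcd1lg2 2.62, Tnfsf9 2.38). Anti-inflammatory and scavenger genes were lower in 14 of 19 (median -2.22; Stab1 -4.19, Trem2 -3.54), complement genes in 10 of 12 (median -2.25), lysosomal genes in 12 of 23 (median -1.08), among them Cd63 (-2.86) and the cathepsin genes Ctsl (-2.42) and Ctsd (-2.37), and lipid genes in 7 of 15 (median -0.98; Abca1 -3.47, Apoe -3.08). Chemokine genes other than Ccl17 and Ccl22 were mostly lower, 11 of 19 in all (median -1.13; Ccl8 -5.00), and interferon response genes were higher in 4 of 20 (median 0.40). H2-Eb2 (4.45) and H2-Oa (3.54) were higher, as were Traf1 (3.37) and Relb (1.74), a subunit of NF-kB needed for dendritic cell maturation, S100a4 (4.91) and Zbtb46 (2.46). Tlr7 (-4.11) and Tlr4 (-2.34) were lower, and matrix genes were lower in 8 of 18 and higher in 4 (median -0.67). Further extremes were Cd7 (5.75) and P2ry10 (5.53) above and Mmp13 (-5.27), Cd4 (-5.16), Olfml3 (-5.01), Fcrls (-5.00) and Kcnj10 (-4.71) below. Markers were lower for epithelium (12 of 16, median -1.33; Fabp2 -3.11), stroma (8 of 10, median -1.15), acini (13 of 14, median -1.63), plasma cells (3 of 7, median -0.98), neutrophils (2 of 4, median -1.10) and B cells (2 of 4, median -1.07, with 1 higher), and all 3 cytotoxic cell markers past the filter, of 10 measured, were higher (Klrd1 5.01), a direction the filter favoured.

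Where the colitis cells lay between monocyte and macrophage was measured gene by gene, with 0 set at the colitis splenic monocyte and 1 at the steady-state F4/80hi macrophage. Of 1658 macrophage-high genes chosen on the arrays labelled female, 1343 (81.0%) were also 2-fold apart between those end points, as were 778 of 925 monocyte-high genes (84.1%). For macrophage-high genes the median position was 1.01 (quartiles 0.911 and 1.13) in F4/80hi cells, 0.523 (0.319 and 0.712) in Ly6Chi cells and 0.520 (0.278 and 0.782) in Ly6Clo cells. For monocyte-high genes it was 0.900 (0.792 and 0.996), 0.417 (0.193 and 0.640) and 0.627 (0.317 and 0.925) in the same order. Epithelial genes were among the macrophage-high genes and epithelial signal differed between the arrays placed, so these positions also reflect it. The macrophage identity list had array medians of 8.968 in the colitis splenic, 9.123 in the Ly6Clo and 9.401 in the Ly6Chi array. In the steady-state F4/80hi array its median was 12.15. By that list both CX3CR1int arrays lay near the monocyte, so positions of 0.523 and 0.520 do not describe macrophage identity genes. Over the 515 macrophage-high genes bright in both splenic arrays, chosen after the values were seen, the medians were 1.02, 0.476 and 0.556. Correlations across 11106 genes, which are not independent replicates, were 0.903 between colitis Ly6Chi cells and splenic monocytes, 0.898 between Ly6Chi and F4/80hi cells, 0.921 between Ly6Clo and Ly6Chi cells, 0.870 between Ly6Clo and F4/80hi cells and 0.846 between Ly6Clo cells and splenic monocytes. Over all probe sets the first pair of values was 0.962 and 0.968, so the order of Ly6Chi cells' likeness to monocytes and macrophages depended on the genes used. The lowest named here, 0.710, was between resident macrophages and steady-state splenic monocytes, and colonic CX3CR1hi pairs reached 0.984 for colitis and steady-state F4/80hi cells and 0.979 for resident and reconstituted cells.

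**Figure D3:**
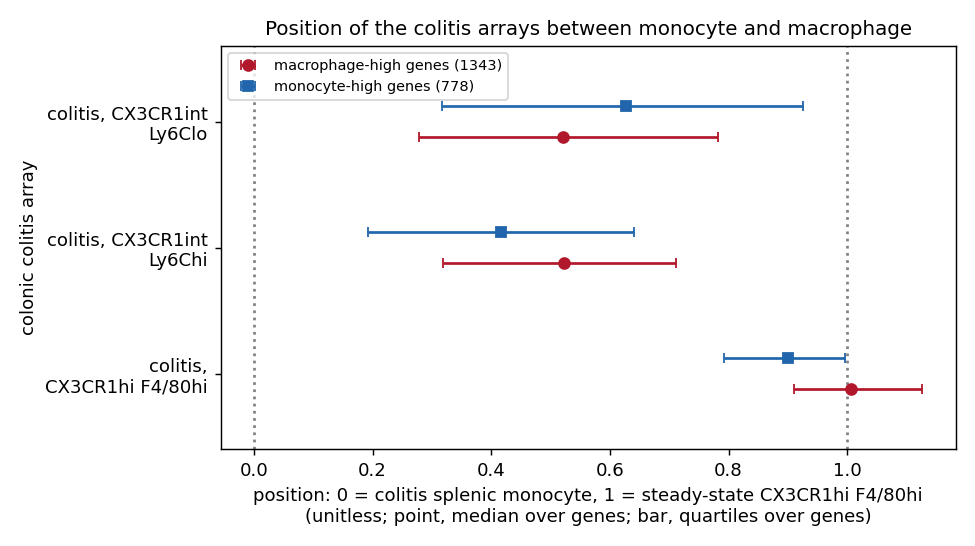
Position of each colonic colitis array between the colitis splenic monocyte (0) and the steady-state CX3CR1hi F4/80hi macrophage (1), unitless, for 1343 macrophage-high genes (red circles) and 778 monocyte-high genes (blue squares); points are medians and bars quartiles over genes. F4/80hi cells lie at 1.01 and 0.900, and both CX3CR1int arrays lie between the end points; the macrophage-high genes include epithelial genes.

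The sorted populations were then compared across conditions with limma, taking 4 colonic CX3CR1hi, 2 colonic CX3CR1int and 2 splenic Ly6Chi arrays. Arrays of a population differed in colitis, origin, Ly6C or sex, so the test asked whether populations differed by more than that spread, and p-values measure only the spread between these arrays. In contrasts with splenic cells, the organ and its handling cannot be told apart from the cell population. Immediate early genes, which also respond to handling, rose there in 19 of 20 for CX3CR1hi and 11 of 20 for CX3CR1int cells. Between colonic CX3CR1hi cells and splenic monocytes, macrophage genes rose: Il10 by 5.57 ± 0.33 (SE; limma adjusted p 1.87e-05), C1qa by 5.55 ± 0.36 (limma adjusted p 2.69e-05), Mertk by 4.73 ± 0.29 (limma adjusted p 2.06e-05) and Stab1 by 6.31 ± 0.28 (limma adjusted p 7.27e-06). Chil3 was -7.20 ± 1.04 (limma adjusted p 9.98e-04) and Serpinb10 -8.06 ± 0.61 (limma adjusted p 4.61e-05). In this contrast 2374 of 10673 genes rose and 3092 fell, 1628 and 961 of them at least 2-fold. Every named gene past the threshold, in each of the contrasts, had all arrays of 1 population above all arrays of the other, which the choice of large changes favours and which adds no evidence. With sex as labelled as a block 2307 rose and 2890 fell, with quantile normalization 2589 and 2523, and over genes bright in both splenic arrays 1264 and 3162. The block took the steady-state splenic array as female although it carried Y-linked RNA, so counts with this block are not fully adjusted for sex.

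Macrophage identity genes rose in 11 of 16 in that contrast, also 11 adjusted over the list alone (median 2.36; camera adjusted p 9.82e-06, and adjusted p = 0.428 with an estimated correlation). Chemokine genes rose in 13 of 18 and fell in 1, 13 and 2 adjusted over the list alone (median 2.72; camera adjusted p 1.15e-05, adjusted p = 0.428 with an estimated correlation), with Ccl8 at 6.23 ± 0.55 and Pf4 at 6.11 ± 0.22. Immediate early genes rose in 19 of 20 (median 1.45; camera adjusted p 3.50e-06, adjusted p = 0.428 with an estimated correlation), and complement genes in 7 of 10, 9 adjusted over the list alone (camera adjusted p 4.62e-05, adjusted p = 0.428 with an estimated correlation). Anti-inflammatory and scavenger genes rose in 11 of 18, Gas6 at 5.50 ± 0.21 among them, and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p 5.88e-05, adjusted p = 0.428 with an estimated correlation). MHC class II genes rose in 7 of 12 (H2-Eb1 1.99, H2-Ab1 1.31; camera adjusted p 0.00613, adjusted p = 0.552 with an estimated correlation). Monocyte identity genes fell in 10 of 13, 11 adjusted over the list alone (median -2.33; S100a4 -5.28, Ccr2 -2.33; camera adjusted p 0.00113, adjusted p = 0.594 with an estimated correlation), and interferon response genes in 13 of 20 with 2 higher (median -1.38; Oas3 -3.96, Irf7 -2.40; camera adjusted p 0.00441, adjusted p = 0.594 with an estimated correlation). Ptgs2 (5.05), Il1b (2.56), Tnf (2.14), Itgax (3.13) and Cd86 (2.00) rose and Nod2 fell (-1.08). Cx3cr1, which defined the sort, rose by 0.83 (limma adjusted p 0.0259), and Adgre1 differed by 0.81 (limma adjusted p 0.0847) and Il6 by 0.50 (limma adjusted p 0.177), neither past the threshold. All 16 epithelial markers rose (median 5.27; camera adjusted p 1.23e-11, adjusted p = 0.428 with an estimated correlation), and epithelial genes such as Muc3 (7.05), Zg16 (6.96), Pigr (6.85) and Krt19 (6.66) were among the largest changes. Plasma cell markers rose in 5 of 7 and fell in 1 (camera adjusted p 0.0394, adjusted p = 0.594 with an estimated correlation), and stromal markers rose in 3 of 10 (median 0.85; camera adjusted p 0.00910, adjusted p = 0.594 with an estimated correlation). Upward calls came also for the cell cycle (10 of 26), costimulation (5 of 9), matrix (10 of 19, with 3 lower), lysosomal (8 of 23) and inflammatory mediator lists (7 of 15, with 2 lower), at camera adjusted p from 5.45e-04 to 0.0291 (adjusted p = 0.428 to 0.594 with an estimated correlation). Of 32 lists 16 were called by camera, and 0 with an estimated correlation, as in the other contrasts; the lipid list had a median of -0.16 and a mean of 0.30, and the B cell list a median of -0.28 with direction up, neither called. Without the steady-state splenic array 1567 genes rose and 1679 fell, and without the colitis splenic array 1835 fell.

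Between CX3CR1int and CX3CR1hi colonic cells, Cx3cr1 fell by 3.45 ± 0.25 (limma adjusted p 2.10e-04), as the receptor that set the gate, and Il10 fell by 3.61 ± 0.33 (limma adjusted p 4.65e-04). Il6 rose by 3.11 ± 0.28 (limma adjusted p 4.51e-04), Nod2 by 2.46 ± 0.16 (limma adjusted p 1.39e-04), Ccr7 by 4.05 ± 0.56 (limma adjusted p 0.00246) and Flt3 by 4.96 ± 0.49 (limma adjusted p 5.86e-04). The contrast gave 1417 genes higher and 1769 lower, 468 and 1012 at least 2-fold, with sex as labelled as a block 836 and 1156, and over genes bright in both splenic arrays 1401 and 1029. Both CX3CR1int arrays came from male mice with colitis, as did 1 of the 4 CX3CR1hi arrays, and against that array alone the macrophage identity list had medians of -2.30 in Ly6Chi and -3.13 in Ly6Clo cells. Macrophage identity genes fell in 14 of 16, 15 adjusted over the list alone (median -2.33; Adgre1 -2.28; camera adjusted p 4.83e-09, adjusted p = 0.366 with an estimated correlation). Lysosomal genes fell in 13 of 23, 16 adjusted over the list alone (median -0.62; camera adjusted p 1.15e-06, adjusted p = 0.448 with an estimated correlation). Interferon response genes rose in 13 of 20, 16 adjusted over the list alone (median 1.03; Oas3 2.70, Mx1 2.01; camera adjusted p 7.77e-07, adjusted p = 0.448 with an estimated correlation). Against the colitis CX3CR1hi array alone, this list had medians of 0.93 in Ly6Chi and 0.40 in Ly6Clo cells. It was also 0.69 higher in colitis between the F4/80hi arrays, so part of this rise cannot be told apart from colitis. Dendritic cell genes rose in 9 of 19, 12 adjusted over the list alone (median 1.67; Cd209a 4.63; camera adjusted p 7.11e-04, adjusted p = 0.669 with an estimated correlation), and costimulation genes in 5 of 9, 6 adjusted over the list alone (camera adjusted p 0.0121, adjusted p = 0.510 with an estimated correlation). Anti-inflammatory and scavenger genes fell in 10 of 18, 12 with 1 higher adjusted over the list alone (median -1.88; Trem2 -1.97, Cd163 -2.38; camera adjusted p 9.44e-05, adjusted p = 0.448 with an estimated correlation). NF-kB feedback genes rose in 6 of 14, 6 with 1 lower adjusted over the list alone (camera adjusted p 0.0121, adjusted p = 0.366 with an estimated correlation). Inflammatory mediators as a list were not called (3 of 15 higher, 1 lower, camera adjusted p 0.0648), with Il23a (1.62) higher, Tnf (-1.08) lower and Il1b at 0.27 (limma adjusted p 0.290), and Vegfa at 1.09 (limma adjusted p 0.104) was not past the threshold. None of 26 cell cycle genes passed. Ifitm6 (6.05 ± 0.27), Cd7 (5.35 ± 0.21), S100a4 (4.88), P2ry10 (4.54), Klrd1 (4.12) and Itgb7 (3.90) rose, and Fcrls (-5.62), Mmp13 (-5.36 ± 0.28), H2-M2 (-5.13), Ccl8 (-4.44) and Pf4 (-4.38) fell. Epithelial markers fell in 11 of 16 (median -1.47; camera adjusted p 4.92e-06, adjusted p = 0.448 with an estimated correlation), and all 3 tested cytotoxic cell markers, of 10 measured, rose (camera adjusted p 0.00785, adjusted p = 0.366 with an estimated correlation). At most 1 of the 10 reached the array median in any CX3CR1hi array, against 3 in Ly6Clo and 4 in Ly6Chi cells. The brightness filter thus favoured this direction. Complement genes fell in 6 of 10 and chemokine genes in 7 of 18 with 1 higher, and hypoxia and glycolysis genes rose in 5 of 16 and monocyte identity genes in 4 of 13, at camera adjusted p from 0.00423 to 0.0320 (adjusted p = 0.448 to 0.710 with an estimated correlation). The monocyte identity list had an array median of 10.622 in Ly6Chi but 8.216 in Ly6Clo cells, against 8.55 to 9.473 in the CX3CR1hi arrays. The Ly6Clo array median thus did not share that rise. Medians and means differed in sign for the MHC class II list (-0.26 and 0.26), the matrix list (0.03 and -0.39) and pattern recognition receptors (-0.07 and 0.07), none of them called.

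Between CX3CR1int colonic cells and splenic monocytes, which differed in organ as well, inflammatory and costimulation genes rose. Il6 rose by 3.60 ± 0.33 (limma adjusted p 5.67e-04), Il1b by 2.84 ± 0.21 (limma adjusted p 2.70e-04), Vegfa by 4.50 ± 0.52 (limma adjusted p 0.00144), Tnfsf9 by 4.39 ± 0.29 (limma adjusted p 2.61e-04) and Ptgs2 by 5.69 ± 0.99 (limma adjusted p 0.00697). In all 1089 genes rose and 1516 fell, 812 and 526 at least 2-fold, with sex as labelled as a block 951 rose and 944 fell, and over genes bright in both splenic arrays 667 and 1686. Costimulation genes rose in 7 of 9, 9 adjusted over the list alone (median 2.13; Cd83 4.36, Cd86 2.13, Cd80 1.70; camera adjusted p 6.37e-08, adjusted p = 0.258 with an estimated correlation). Inflammatory mediators rose in 9 of 15 and fell in 1, 9 and 2 adjusted over the list alone (camera adjusted p 5.27e-05, adjusted p = 0.290 with an estimated correlation). NF-kB feedback genes rose in 9 of 14, 11 adjusted over the list alone (camera adjusted p 2.68e-06, adjusted p = 0.101 with an estimated correlation), dendritic cell genes in 9 of 19, 11 adjusted over the list alone (Ccr7 3.97, Socs2 5.17; camera adjusted p 4.26e-06, adjusted p = 0.428 with an estimated correlation), and cell cycle genes in 7 of 26, 12 adjusted over the list alone (camera adjusted p 7.76e-07, adjusted p = 0.498 with an estimated correlation). The cell cycle list had array medians of 9.171 in Ly6Clo but 7.145 in Ly6Chi cells, against 6.674 and 6.598 in the steady-state and colitis splenic arrays. Its rise thus came mostly from the Ly6Clo array. Il10 (1.96), Il23a (1.92), Nod2 (1.38), the decoy receptor gene Il1r2 (5.46 ± 0.65) and Nr4a3 (5.49) rose. Cx3cr1 (-2.62), S1pr5 (-3.58 ± 0.19), Ace (-4.09), Tlr7 (-3.51) and Chil3 (-4.54 ± 1.20, limma adjusted p 0.0313) fell. Chil3 was not past the threshold with sex as a block, without the brightness filter or without any 1 of the reconstituted, steady-state splenic, steady-state F4/80hi, colitis F4/80hi and colitis splenic arrays. With only the arrays of both populations Chil3, Ace, Tlr7 and Ptgs2 were not past it, nor were Ace and Tlr7 without the steady-state splenic array and Tlr7 without the colitis splenic array. Monocyte identity genes fell in 2 of 13, 0 adjusted over the list alone (median -1.80; camera adjusted p 0.00844, adjusted p = 0.522 with an estimated correlation). Epithelial markers rose in 15 of 16 (median 3.46; camera adjusted p 1.86e-13, adjusted p = 0.258 with an estimated correlation) and plasma cell markers in 3 of 7 (camera adjusted p 0.00233, adjusted p = 0.428 with an estimated correlation). Stromal markers rose in 1 of 10 (median 0.91; camera adjusted p 0.00284, adjusted p = 0.522 with an estimated correlation) and cytotoxic cell markers in 2 of 3 (median 2.72; camera adjusted p 0.0252, adjusted p = 0.290 with an estimated correlation). Immediate early genes rose in 11 of 20, chemokine genes in 8 of 18, complement genes in 5 of 10, MHC class II genes in 5 of 12, hypoxia and glycolysis genes in 7 of 16 and matrix genes in 7 of 19 with 2 lower, at camera adjusted p from 7.14e-08 to 0.0138 (adjusted p = 0.258 to 0.428 with an estimated correlation). Macrophage identity genes went both ways (median -0.15, mean 0.25, camera direction up, adjusted p 0.362), as did interferon response genes (median -0.14, mean 0.06) and chemokine receptors (median -0.36, mean 0.05), neither called. Without the steady-state splenic array 438 genes rose and 297 fell, without the colitis splenic array 545 and 471, and without the colitis Ly6Chi array 1704 rose.

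Signal from other cells and from both sexes was read in each array. Epithelial markers had medians of 11.19 in the resident, 10.33 in the reconstituted, 9.99 and 10.01 in the steady-state and colitis F4/80hi, 9.01 in the Ly6Chi and 8.77 in the Ly6Clo arrays, against 5.04 and 5.54 in the steady-state and colitis splenic arrays. Plasma cell markers were highest in the Ly6Chi array (9.75) and stromal markers in the colitis F4/80hi array (7.42). Markers of T cells, eosinophils, mast cells, erythroid cells and endothelium had medians between 4.42 and 6.26 in all arrays. Acinar genes had medians of 7.34, 6.64 and 7.45 in the resident, colitis F4/80hi and Ly6Chi arrays and between 5.02 and 5.63 in the other 5. Xist stood at 12.17 and 12.28 in the resident and reconstituted arrays, at 10.04 in the steady-state splenic array and at most 4.78 in the arrays labelled male.

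**Figure D4:**
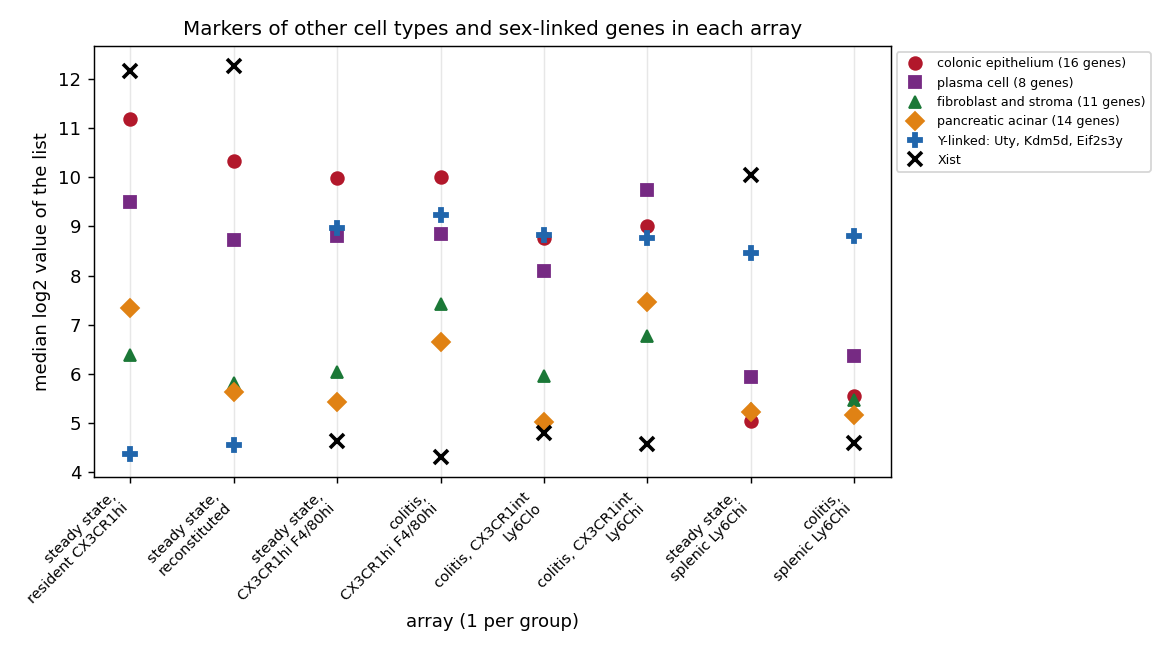
Median log2 value, in each of the 8 arrays, of marker lists of other cell types and of 3 Y-linked genes, and the value of Xist. Epithelial markers lie between 8.77 and 11.19 in colonic and at 5.04 and 5.54 in splenic arrays, and the steady-state splenic array labelled female shows both Xist (10.04) and Y-linked signal.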

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

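All tests in this part that weigh an explanation were chosen only after the result was seen. In the colonic CX3CR1hi population, an array was picked out when its gap to the nearest of the other 3 was large against the range of the 4. This happened for 5 of 58 items tested, and chance alone gives about 1 in 20. The colitis F4/80hi array stood apart for the median of the anti-inflammatory and scavenger list (10.65 against 10.14 to 10.21) and of ribosomal protein genes (11.78 against 11.75). Gene by gene the ribosomal list was instead lower in that array. Its median difference was -0.17 relative to all genes against the steady-state F4/80hi array and -0.09 against the resident array. The resident array stood apart for neutrophil markers (4.645 against 4.883 to 4.906), near the floor of the arrays, and for plasma cell markers (9.491 against 8.733 to 8.853). Il12b was lowest in the steady-state F4/80hi array (5.669). Colitis and steady state differed in opposite directions in the colon and the spleen for the interferon response list, with medians of 0.69 in F4/80hi cells and -0.13 in splenic monocytes. For epithelial markers the medians were -0.03, with none of 16 at least 2-fold apart, and 1.67 over the 6 past the filter in the spleen. Of the 16, 1 reached the array median in the steady-state and 6 in the colitis splenic array, so the filter favoured this direction. Over all 16 the array medians were 5.04 and 5.54. These differences between tissues were not tested.

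The steady-state splenic array labelled female carried Y-linked RNA, with a median excess of Uty, Kdm5d and Eif2s3y over the other female arrays of 3.92, and Xist as well. The excess of 3.92 argues against a sample all female as labelled, and a Xist level 5.26 above the highest of 5 male arrays argues against a sample all male with a wrong label. Its Y-linked signal was 83.1% (median; 77.8% to 90.0%) of that in the colitis splenic array and its Xist signal 21.6% of that in the female colonic arrays, and these shares summed to 1.05. RNA of both sexes in this sample may therefore account for the pattern, whether from mice pooled by design or from mixing later. The design gives sex but no sample of known mixture, and no biological explanation was tested.

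Pancreatic enzyme genes, found outside the comparisons' lists, were above the higher splenic array by a median of 2.12 in the resident, 1.42 in the colitis F4/80hi and 2.23 in the colitis Ly6Chi array. Carried-over colonic epithelium is argued against, because the Ly6Chi array exceeded the reconstituted array by 1.82 in acinar genes and was below it by -1.32 in epithelial markers. Colitis stays open, since the list was 1.34 higher in colitis between the F4/80hi arrays, with 10 of 14 genes at least 2-fold higher, but differed by -2.55 between both steady-state CX3CR1hi arrays, which colitis does not explain. Pancreatic tissue carried over during dissection may remain but is not singled out. The 9 acinar genes that no rule had named differed by 2.13 between Ly6Chi and Ly6Clo cells and 8 of them by at least 2-fold. Acinar genes may vary together whatever their source, so this cannot decide it. Both gates were from colitis colon, and the labels do not say whether they shared a dissection. The 2 islet genes measured stayed at or below 4.82, and the sort on CX3CR1 would remove whole acinar cells but not free RNA.

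Immediate early genes were higher in the colitis than in the steady-state splenic array, in 10 of 19. Colonic RNA carried over may account for the epithelial transcripts there, since all 13 genes dim in the spleen and at least 64-fold brighter in steady-state F4/80hi cells were higher in the colitis splenic array (100%), against 50.2% of equally dim genes level between colon and spleen. These 13 were chosen on the mean of both splenic arrays, without the epithelial markers and the genes named for this comparison, and their median share was 0.841% of the colonic level. Epithelial genes such as Clca1, Muc3, Pigr and Zg16 were among them. Genes of 1 source may vary together, so the 13 are not independent and cannot decide how the transcripts came there. Of the 16 epithelial markers 4 had a share at or below 0 (lowest -0.817%). The 10 immediate early genes past 2-fold would need a median of 27.0% of the colonic level (7.80% to 66.0%). Of these, 9 needed more than the highest epithelial marker (8.79%, with a median of 0.454%). They were chosen as past 2-fold from a list already bright in the steady-state splenic array (median 8.581), which by construction favours a high share. Carry-over at the median epithelial share is thus too small for a 2-fold rise of these 10 genes, and the rest of the list was not weighed. Colitis itself, with a list median of 1.01, cannot be told apart from sex, the mixed-sex sample and unmatched handling of these arrays, and stays open.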

How the results depend on the processing

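The counts over genes bright in both splenic arrays, those without marker genes, list medians against the other steady-state CX3CR1hi array and the colitis splenic array as comparison for resident macrophages were chosen after seeing the data. No paired analysis was possible because the labels give no shared replicate numbers. All 18 values for the position between monocyte and macrophage stayed within the quartiles over genes. The largest change was in monocyte-high genes in Ly6Chi cells, from 0.417 to 0.283 with genes at least 4-fold apart, and for macrophage-high genes Ly6Chi and Ly6Clo cells changed places with a ratio of medians (0.478 and 0.545) and over genes bright in both splenic arrays (0.476 and 0.556). All 18 counts without marker genes changed by less than 1.5 times, but this removed only the listed markers. For resident against splenic cells 10652 genes became 10576, and other epithelial genes such as Muc3 and Zg16 stayed in. These counts therefore cannot show whether signal from other cells affects the results. Over all probe sets 5 of the correlations changed by less than 0.05 and 5 by more. The latter were Ly6Chi cells with splenic monocytes (0.962) and with F4/80hi cells (0.968), which changed places, Ly6Clo cells with F4/80hi cells (0.958) and with splenic monocytes (0.941), all in colitis, and resident macrophages with steady-state splenic monocytes (0.9095). For named genes between single arrays, 368 values stayed within the yardstick spread, 41 moved and 11 changed sign. In the population test 957 values kept their side of the threshold and 34, all for CX3CR1int against splenic cells, kept their direction but lost it (Chil3, Arhgef37, Ace, Abcd2, Tlr7, Zfyve9, Serpinb10, Cyp2ab1, Lypd8 and Ptgs2). Signals near background, around 4 to 5, have compressed differences, so a low gene that is not apart is not shown to be equal. Except where the number of genes counted or arrays fitted was reduced by construction, the cause was not tested.

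A filter at the 75th percentile counts fewer genes. It left 35 higher and 49 lower for reconstituted against resident, 1095 higher for resident against splenic, 54 and 15 for colitis in F4/80hi cells, and 26 higher for colitis in splenic monocytes. It left 444 and 225 for Ly6Chi against splenic cells, 546 lower for Ly6Chi against F4/80hi, 374 and 353 for Ly6Clo against Ly6Chi, 494 and 692 for Ly6Clo against F4/80hi, and 201 lower in the yardstick. Counting only the 9097 genes bright in both splenic arrays left 34 and 18 for reconstituted against resident, 811 higher and 1057 lower for resident against splenic, 39 and 13 for colitis in F4/80hi cells, and 35 and 1 for colitis in splenic monocytes. It left 387 and 393 for Ly6Chi against splenic cells, 472 and 452 for Ly6Chi against F4/80hi, 362 and 407 for Ly6Clo against Ly6Chi, 525 and 627 for Ly6Clo against F4/80hi and 23 and 47 in the yardstick. The direction with more genes thus changed for reconstituted and for resident macrophages, for Ly6Chi against both splenic and F4/80hi cells and for Ly6Clo against Ly6Chi cells. In comparisons with a splenic array this choice removes, by construction, genes higher in the colonic array, so the change there supports no conclusion. In the other comparisons it removes genes dim in the spleen. Of 16 epithelial and 14 acinar genes, 1 each reached the array median in the steady-state splenic array. The changes of direction between colonic arrays therefore support no conclusion either.

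With the steady-state F4/80hi in place of the resident array, the reconstituted array had 159 genes higher and 57 lower, and Cpb1 (0.037), Cpa1 (0.70), Ctrb1 (0.70), Rnase1 (0.31) and Ctrl (0.86) changed sign. With the resident array as steady state, colitis F4/80hi cells had 67 higher and 401 lower, and Cpa1 (-0.36), Ctrb1 (-0.69), Rnase1 (-0.40), Cpb1 (-0.71), Snhg17 (0.48) and DQ267102 (0.42) changed sign. The yardstick with the reconstituted array gave 57 and 159. Without a filter, list medians changed sign for matrix genes (0.0095) and neutrophil markers (-0.017) in colitis F4/80hi cells and for B cell markers in Ly6Clo against F4/80hi cells (0.24). Against the other steady-state array, among lists outside the central 95% of random lists, they changed sign for epithelial (0.33), plasma cell (0.012) and patrolling monocyte markers (-0.0013) in reconstituted cells and for the MHC class II (0.0746), chemokine receptor (0.0303) and matrix lists (0.0415) in colitis F4/80hi cells.

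In the population test a 2-fold minimum left 961 lower for CX3CR1hi against splenic, 468 higher and 1012 lower for CX3CR1int against CX3CR1hi and 526 lower for CX3CR1int against splenic cells. Genes bright in both splenic arrays gave 1264 and 3162, 1401 and 1029, and 667 and 1686 in that order of contrasts. For the contrasts with splenic cells this choice favours lower genes by construction. For CX3CR1int against CX3CR1hi cells it removes colonic genes dim in the spleen, so the changed direction there supports no conclusion. Sex as labelled as a block gave 836 higher and 1156 lower for CX3CR1int against CX3CR1hi and 944 lower for CX3CR1int against splenic cells, and only the arrays of both populations gave 592 and 355 for the latter. With an estimated correlation, camera called 0 lists in each contrast, against 16, 14 and 17. Leaving out each array in turn gave 1567 to 2787 higher and 1679 to 3613 lower for CX3CR1hi against splenic cells. The ranges were 999 to 1825 and 1380 to 1839 for CX3CR1int against CX3CR1hi, and 438 to 1704 and 297 to 2059 for CX3CR1int against splenic cells. Where this left 1 array in a population, it was assumed to vary like the others.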

Other observations

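Of 5 tested genes of red pulp macrophages 3 fell between CX3CR1int and CX3CR1hi cells (median -2.09; camera adjusted p 0.0121, adjusted p = 0.448 with an estimated correlation), and between single arrays they were lower in 4 of 5 in Ly6Clo (median -2.87) and in 3 of 5, with 1 higher, in Ly6Chi cells (median -2.25) against colitis F4/80hi cells. Patrolling monocyte genes were lower in 6 of 10 in CX3CR1int than in splenic cells and higher in 1 (median -1.37; camera adjusted p 0.0138, adjusted p = 0.258 with an estimated correlation). Cytotoxic cell markers were low in most arrays, with medians of 5.50 in Ly6Clo and 5.24 in Ly6Chi cells and at most 5.03 elsewhere. Ribosomal protein genes differed little, with none of 15 past 2-fold in any of the 9 comparisons of single arrays and none past the threshold in any contrast.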
